A study of Mus musculus with 2 samples.

How the data were processed

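The series holds 2 MNase-seq libraries of Brg1fl/fl ES cells, 1 treated with ethanol and 1 with 0.8 µM tamoxifen. Per the labels' protocols, nuclei of 20000000 cells were digested with a range of MNase amounts, and the mononucleosome band of the 12 U digest was sequenced. The authors deposited 1 list of called nucleosomes per library, with chromosome, start, end, a name and a score for each call. Reads were aligned with Bowtie 0.12.9 and the build is mm9, per the submitters' processing notes. The caller, its cutoffs, the treatment of duplicate reads and the definition of the score are not given in the sources used here. The authors' score ran from 50.1 to 3250 in both lists, with 757 ethanol calls and 848 tamoxifen calls at the maximum, and it was used only to describe, rank or filter calls within a list. Positions are given as the files hold them. All starts and ends lie on a 10 bp grid, calls do not overlap, and widths run from 80 to 240 bp, so shifts of a few bp cannot be resolved. Because only nucleosomes that passed the authors' cutoffs are listed, a missing call is not an absent nucleosome, and deeper sequencing by itself would add calls. The depth in reads is unknown, and counting intervals treat calls as independent counts.

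Groups were taken from the sample titles. With 1 library per group no test was made. The centre of a call was the midpoint of its start and end. For position shift, each centre was taken to the nearest centre of the other library, beside 10 displacements of 1000 to 10000 bp as the chance level. For spacing, all pairs of centres up to 2000 bp apart were counted in 5 bp bins and smoothed over 15 bp. Peak k was the highest bin within 60 bp of k times 190 bp, and the slope of the first 5 peaks on their order was the repeat length. Windows of 10 kb and whole chromosomes were compared after scaling to the number of calls per library, with exact Clopper-Pearson intervals for the split of the calls, and 20 random binomial splits gave the number of windows past the fold limit if calls were independent between libraries, which they are not. Chromosome densities used the highest position in either list as the length. Shares have Wilson intervals and counts exact Poisson intervals, and the intervals of the periodicity contrast treat numbers of pairs as Poisson counts on a log scale. These comparisons, their alternatives and the rule for named regions were fixed before the data were examined, while the periodicity contrast, arrays, density classes and single-library stretches were added later. For stretches, calls of a list were divided by score into 20 classes.

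The rule for named genes asked for an annotation of mm9. Without it no gene is named from coordinates, and the 5 windows of 10 kb with the highest and the 5 with the lowest log2 ratio, among windows at or above the median scaled count, are given instead, ties being taken in chromosome order. The gene table at hand is on another build, GRCm38.p6, and served only to look up the chromosome of Smarca4. Spacing at motif sites, promoter nucleosomes by gene list and the Smarca4 gene, which had been planned, were not analysed here for the same reason. The alternatives were calls at or above the median score, thinning of the tamoxifen list, autosomes only, and other limits for distance, smoothing, peaks, window size, fold and scaling.

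The procedures were tested on simulated data. From about as many simulated calls as in the ethanol library, repeat lengths of 180, 190 and 200 bp were recovered with an error of at most 0.5 bp, but these calls were more periodic than the libraries. In 20 draws at 190 bp with weaker periodicity, a contrast of 1.405 to 1.422, the recovered values ran from 187.5 to 192.0 bp. Of 200 simulated windows changed 2-fold among 20000, 97.0% were found, that is, over 1.5-fold higher. How many unchanged windows passed the same limit is not given here. Of 20 simulated stretches of 8 lost calls, 90.0% were among the 20 highest. All other simulated losses were independent of each other, and the simulated list was smaller than those of the libraries. The 90.0% therefore does not carry over to the libraries. The simulated windows had counts like those of 100 kb windows. Windows of 10 kb had a median scaled count of only 4.49, so the 97.0% does not carry over to them. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.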

Results

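Nucleosome positions were profiled by MNase-seq in mouse embryonic stem (ES) cells whose Brg1 alleles are floxed and which carry a tamoxifen-inducible Cre recombinase under an actin promoter. Brg1, encoded by Smarca4, is the ATPase of esBAF, the SWI/SNF-family remodeling complex of ES cells. Micrococcal nuclease digests the linker DNA between nucleosomes, so that the DNA recovered from the mononucleosome band marks where nucleosomes sat. Tamoxifen at 0.8 µM, or ethanol as the vehicle, was present for 24 hours, after which the cells grew for 48 hours without it. Each group had 1 library, so the comparisons below have no replicate check, no test was run and no p-value is given. Intervals are 95% and cover counting error only. Values for the 19 autosomes describe the same 2 libraries and are not replicates. The question posed by the series is whether esBAF promotes the spacing of nucleosomes, in particular beside the binding sites of pluripotency factors. The Smarca4 gene itself, promoters and motif sites were not analysed here, because no genome or annotation of the build of the files, mm9, was at hand.

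The nucleosome landscapes of the 2 libraries had the same general make-up, with more nucleosomes called after tamoxifen. The ethanol library held 1300009 called nucleosomes (Poisson interval 1297775 to 1302246) and the tamoxifen library 1424844 (1422505 to 1427185), which is 9.6% more. The calls covered 145.9 and 159.9 Mb and had mean widths of 112.26 and 112.24 bp. The authors' score per call had a median of 86.0 in each list. On the autosomes the median distance from the centre of a call to the next was 820 bp with ethanol and 780 bp with tamoxifen, so the lists are not complete maps of the nucleosomes. The number of sequencing reads behind the calls is unknown.

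Chromosomes 8 and 12 carried more called nucleosomes per Mb than the other 17 autosomes, in both libraries. Chromosome 8 had 894.0 calls per Mb with ethanol (Poisson interval 888.9 to 899.1) and 964.9 with tamoxifen (959.6 to 970.2). For chromosome 12 the densities were 816.0 (811.0 to 821.1) and 898.0 (892.6 to 903.3). The other autosomes lay between 360.8 and 654.3 calls per Mb in the ethanol library, with a median of 490.8, and between 405.8 and 706.6 in the tamoxifen library, with a median of 533.8. Chromosome 8 thus stood at 1.82 times the median of the others with ethanol and 1.81 times with tamoxifen, and chromosome 12 at 1.66 and 1.68 times. The X chromosome was the other extreme among the larger chromosomes, with 59.6 calls per Mb with ethanol and 67.4 with tamoxifen. Median scores within the ethanol list were 101.6 on chromosome 8 and 98.2 on chromosome 12, against 82.7 to 86.0 on the other autosomes.

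**Figure D1:**
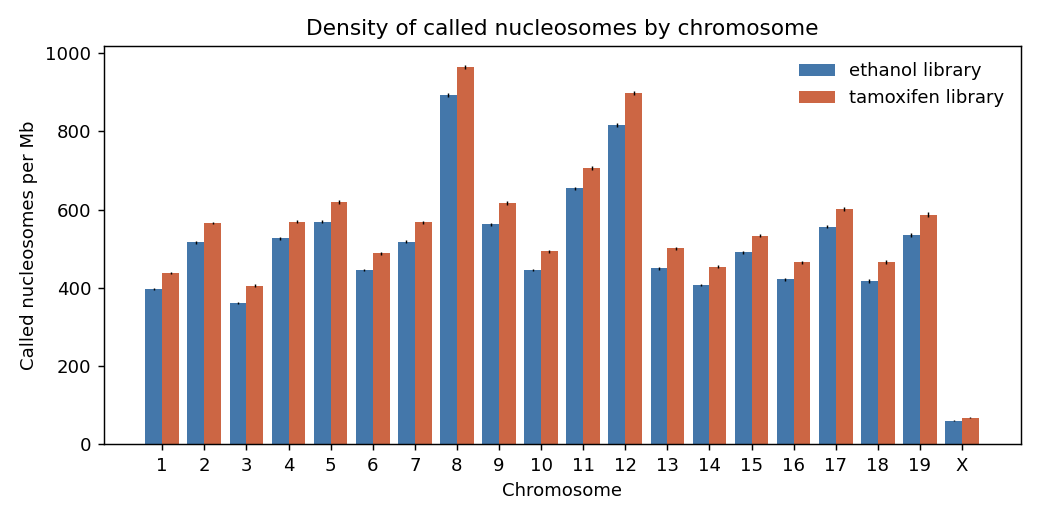
Called nucleosomes per Mb (vertical axis) on each autosome and the X chromosome in the ethanol and tamoxifen libraries, with 95% Poisson intervals as error bars. Chromosomes 8 (894.0 and 964.9 per Mb) and 12 (816.0 and 898.0 per Mb) stand above the other autosomes in both libraries.

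Scaled to the library totals, whole autosomes differed little between the treatments. The log2 ratio of tamoxifen over ethanol ranged from -0.02 to 0.04 over the 19 autosomes. Its exact interval lay above 0 for 4 of them (chromosomes 3, 13, 14 and 18) and below 0 for 4 (chromosomes 4, 8, 11 and 17). On the X chromosome the log2 ratio was 0.045 (0.006 to 0.084).

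Whether nucleosomes moved after tamoxifen was examined by taking each call to the nearest call of the other library. Nucleosome positions were shared far more often than displaced positions, though under the 20 bp limit most calls had no partner. Of the nucleosomes called in the ethanol library, 44.44% (Wilson interval 44.35 to 44.52%) had a tamoxifen call within 20 bp, and the median distance was 30 bp. After displacing the ethanol calls by 1000 to 10000 bp, 4.27 to 4.64% did so, with median distances of 350 to 375 bp. In the other direction, 40.54% (40.46 to 40.62%) of the tamoxifen calls had an ethanol call within 20 bp, against 3.90 to 4.23% after displacement, and the median distance was 35 bp. Sharing rose with the score of the nucleosome, from 28.59% among ethanol calls scored below 65.3 to 64.07% among those scored 129.1 or more. It was also higher on chromosomes 8 (50.54%) and 12 (50.09%) than on the other 17 autosomes, where it lay between 42.58 and 43.76%. On the X chromosome it was 46.01%. The displaced share was taken over all chromosomes only, so it is not known how far these differences follow call density. With no second ethanol library, the share that 2 libraries of untreated cells would reach is unknown, so no part of the unshared positions can be assigned to tamoxifen.

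Genome-wide spacing gave no settled order of the nucleosome repeat lengths of the 2 libraries. The distances between pairs of calls peaked at 190, 380, 570, 770 and 965 bp with ethanol and at 190, 380, 580, 765 and 970 bp with tamoxifen, which gives repeat lengths of 194.0 and 194.5 bp. The repeat length was higher with tamoxifen on 7 of the 19 autosomes, lower on 11 and equal on 1. Per autosome it averaged 192.66 bp (SD 4.31 across the 19 autosomes) with ethanol and 192.16 bp (SD 2.74) with tamoxifen. The order turned when the distances were smoothed over 45 bp (193.0 bp with ethanol and 190.5 bp with tamoxifen) and after thinning the tamoxifen list (194.0 and 192.5 bp). In simulated calls with slightly stronger periodicity than the ethanol library, the recovered repeat length was off by up to 2.5 bp, more than the 0.5 bp between the libraries. Among successive calls, 27.41% (Wilson interval 27.33 to 27.48%) with ethanol and 28.17% (28.09 to 28.24%) with tamoxifen were neighbours 140 to 400 bp apart, with a median distance of 235 bp in each. The neighbour share was higher with tamoxifen on 19 of 19 autosomes but not on the X chromosome, where it was 21.20% with ethanol and 20.71% with tamoxifen. Among calls at or above the median score of their own list it was 18.35% in both libraries. After random thinning of the tamoxifen list to the size of the ethanol list it was 25.88%, a loss that removing calls brings by construction. Mean neighbour distances were 254.51 bp with ethanol and 255.91 bp with tamoxifen, and the mean was higher with tamoxifen on 18 of 19 autosomes, by 1.55 bp on average (SD 0.80 across autosomes). Over all chromosomes this order turned when neighbours were limited to 300 bp (213.56 and 213.11 bp).

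By 1 measure, the periodicity contrast, the regularity of the pattern differed more clearly than its period. The periodicity contrast was taken as the number of pairs 350 to 410 bp apart over the number 260 to 320 bp apart, which sets pairs separated by 2 repeats against pairs between repeats. These distance limits were chosen after the distances had been seen. The contrast was 1.397 (interval 1.383 to 1.411) with ethanol and 1.546 (1.531 to 1.560) with tamoxifen, a ratio of 1.107 (1.092 to 1.122). It was higher with tamoxifen on 19 of 19 autosomes, and on 12 of them the 2 intervals did not overlap. Over autosomes the contrast ran from 1.333 to 1.449 with ethanol and from 1.416 to 1.624 with tamoxifen. On chromosome 6 it was 1.395 with ethanol and 1.624 with tamoxifen, and on chromosome 13, where the libraries were closest, 1.378 and 1.416. On the X chromosome it was 1.150 (1.009 to 1.310) and 1.381 (1.224 to 1.559). Pairs share calls and are not independent, so the intervals are too narrow. With 1 library per group this difference cannot be set against the spread between cultures or digests.

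**Figure D2:**
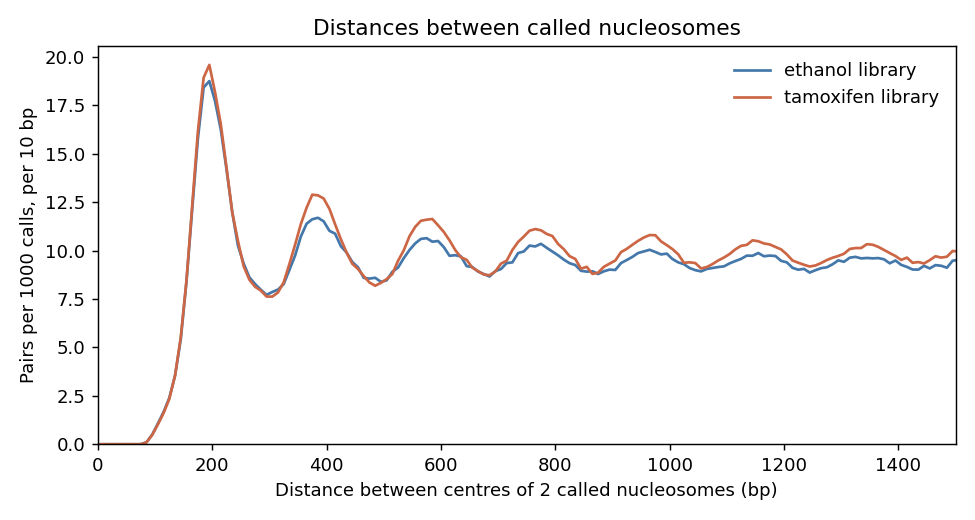
Pairs of called nucleosomes per 1000 calls and per 10 bp (vertical axis) by the distance between their centres in bp (horizontal axis), for the ethanol and tamoxifen libraries. Both curves peak near 190 and 380 bp, and the tamoxifen curve has the higher peaks, with a contrast of 1.546 against 1.397.

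Runs of regularly spaced nucleosomes were present in both libraries, and the runs themselves were partly the same. Arrays of at least 4 successive calls, each 150 to 230 bp from the next, numbered 5069 with ethanol (Poisson interval 4930 to 5211) and 5865 with tamoxifen (5716 to 6017). Shuffling the distances between calls within each chromosome left means of 2635.2 and 3104.1 arrays over 20 shuffles, so that observed arrays were 1.92 and 1.89 times as many. The shuffles also removed the variation of call density along each chromosome, so this excess does not by itself show regular spacing. Unlike the periodicity contrast, the excess was not higher with tamoxifen. The mean spacing within arrays was 192.2 bp with ethanol and 191.9 bp with tamoxifen. Of the ethanol arrays, 25.4% overlapped a tamoxifen array, against 2.7 to 4.5% after displacement by 1000 to 10000 bp. Per 1000 calls there were 3.899 arrays with ethanol and 4.116 with tamoxifen. Thinning the tamoxifen list at random to the size of the ethanol list left 4240 arrays, but random loss of calls breaks runs by construction, so it does not show how much of the difference comes from the number of calls. Only 3 ethanol arrays and 1 tamoxifen array had 10 or more calls. The longest ethanol array, 13 calls with a mean spacing of 182.9 bp, had its outermost centres at 47599206 and 47601401 on chromosome 6, where the tamoxifen library had 10 calls. An array of 11 calls reached from 125641896 to 125643836 on chromosome 8 and an array of 10 from 10868316 to 10869981 on chromosome 16, with 7 tamoxifen calls between the outermost centres of each. The longest tamoxifen array, 10 calls spaced 195.0 bp on average, lay between 114574871 and 114576626 on chromosome 12, where the ethanol library had 7 calls. Coordinates are on mm9.

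Across windows of the genome, the relative gain of calls with tamoxifen was highest where called nucleosomes were sparse. Windows of 100 kb were divided into 10 classes by their scaled calls in both libraries together, a division chosen after the window values had been seen. In the sparsest class the tamoxifen library had 14135 calls and the ethanol library 11507, a log2 ratio of 0.16 (exact interval 0.13 to 0.20) after scaling to the library totals. The ratio fell with each denser class. In the densest class, with 389772 and 372515 calls, it was -0.07 (-0.07 to -0.06). Before scaling, the tamoxifen library had 1.228 times as many calls in the sparsest class and 1.046 times as many in the densest. Read depth is unknown and deeper sequencing by itself would add calls, so this gradient cannot be read as a redistribution of nucleosomes.

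**Figure D3:**
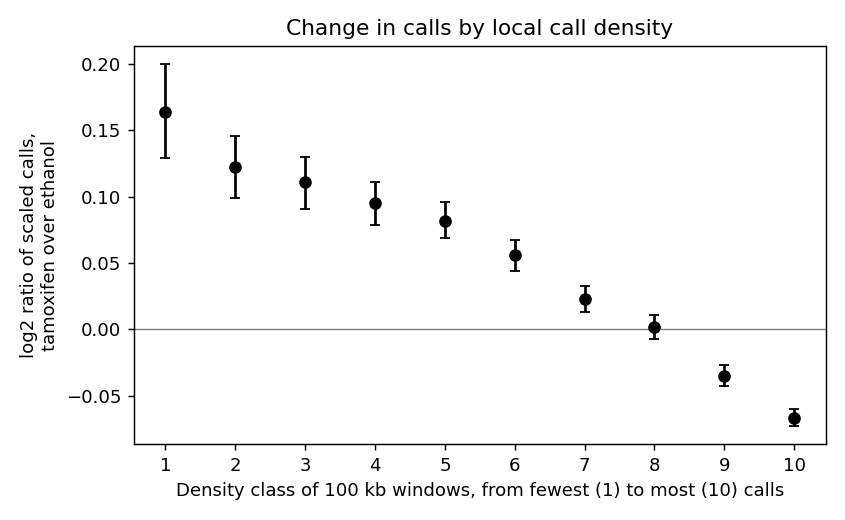
Log2 ratio of scaled calls, tamoxifen over ethanol (vertical axis), in 10 classes of 100 kb windows ordered by their number of calls (horizontal axis), with exact 95% intervals as bars. The ratio falls from 0.16 in the sparsest class to -0.07 in the densest.

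Among windows at or above the median scaled count, most differed by no more than 1.5-fold between the libraries. Windows below that median were not compared one by one. Of 117409 windows of 10 kb at or above the median scaled count, 9439 were over 1.5-fold higher with tamoxifen and 10738 over 1.5-fold lower, whereas splitting each window's calls at random between the libraries gave 24102.6 and 23917.2 on average. At 100 kb, 22 windows were higher and 9 lower, against 132.6 and 121.4 from random splits. Random splits treat calls as independent, whereas 57.02% of ethanol calls had a tamoxifen call within 40 bp, so they overstate the noise and real differences of this size could lie below them. The intervals of single windows rest on the same assumption. The windows that ranked highest in the tamoxifen library at 10 kb were chromosome 17, 75240001 to 75250000, and chromosome 19, 61070001 to 61080000. Each had 1 ethanol call and 10 tamoxifen calls, a scaled ratio of 9.12 (exact interval 1.30 to 396). They were followed by 6 windows tied at 1 and 9 calls, of which those taken were on chromosome 2 (52340001 to 52350000), chromosome 6 (33050001 to 33060000) and chromosome 9 (74780001 to 74790000), with a ratio of 8.21 (1.14 to 360). The window ranked lowest, chromosome 2 from 102310001 to 102320000, had 9 ethanol calls and 1 tamoxifen call, a ratio of 0.101 (0.00231 to 0.732). Next came chromosome 1 from 54200001 to 54210000, with 8 calls and 1 call, and chromosome 10 from 96180001 to 96190000, with 11 and 2. The last of the 5 places went to 2 windows on chromosome 1, at 137130001 to 137140000 and at 188220001 to 188230000, from 5 windows tied at 9 and 2 calls. These are extremes of 117409 windows, so their intervals do not allow for the selection.

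Stretches with several nucleosomes called in a single library were also ranked, by a rule chosen after the data had been seen. A stretch is a run of calls that all lie more than 100 bp from any call of the other library, with no call of that library between them. Its value is the sum over its calls of the negative log10 of the unmatched share among calls of like score. The stretch with the highest value in the ethanol library lay on chromosome 9, with centres from 21468391 to 21470241, and held 8 calls with scores of 54.5 to 237.2. The tamoxifen library had no call between 21468086 and 21470691, a gap of 2605 bp. The value of this stretch was 5.13. The next ethanol stretch, 6 calls on chromosome 15 from 89200466 to 89202516, reached 4.67. Among stretches called with tamoxifen alone, 4 calls on chromosome 3 from 144210576 to 144211061 reached 5.54 and 9 calls on chromosome 18 from 54267701 to 54278721 reached 5.03. The value of the ethanol stretch on chromosome 9 therefore did not exceed the highest value in the opposite direction. The comparison is uneven, since there were 394548 tamoxifen stretches against 340965 with ethanol. The tamoxifen stretches named also differ from the chromosome 9 stretch in number of calls and span.

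**Figure D4:**
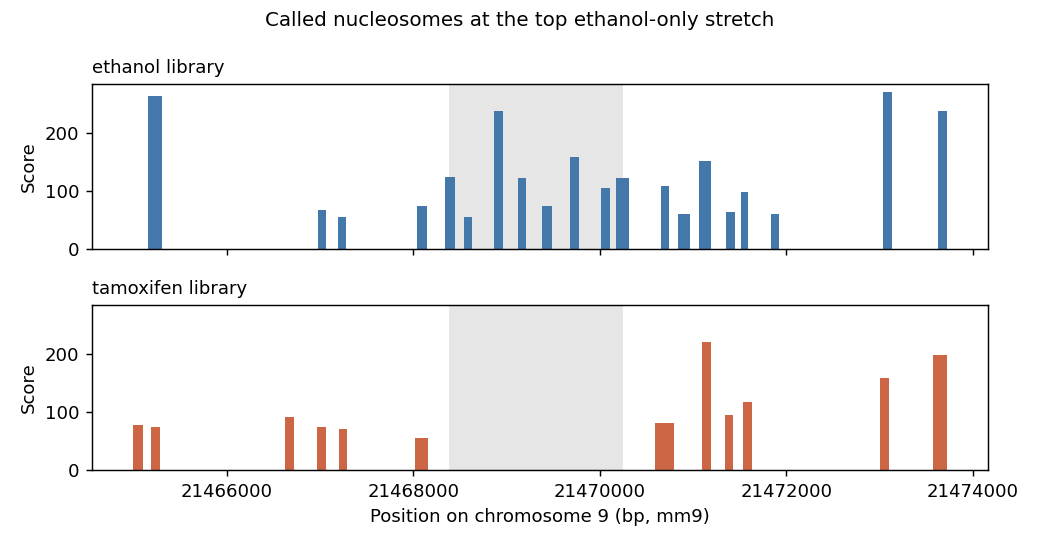
Calls of the ethanol library (upper panel) and the tamoxifen library (lower panel) on chromosome 9 by position in bp on mm9, with bar width the extent of each call and height the authors' score. The shaded span holds 8 ethanol calls and no tamoxifen call.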

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

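The thinning of arrays and the alternatives for the periodicity contrast without chromosomes 8 and 12, by partner and with other distance limits were chosen after the data had been seen. The share of ethanol calls with a tamoxifen call within 20 bp was 44.44%. It moved to 42.69% when both lists were cut to calls at or above the median score, and to 40.56% after thinning the tamoxifen list. Each of these removes partners by construction, so the 42.69% does not mean that high-scoring calls were shared less. The share was 30.65% within 10 bp and 57.02% within 40 bp. The difference in repeat length, tamoxifen minus ethanol, was 0.5 bp, but 5.0 bp for calls at or above the median score and for the first 3 peaks, -1.5 bp after thinning and -2.5 bp with smoothing over 45 bp, so its direction is open. The neighbour share, 0.76 percentage points higher with tamoxifen, was -1.53 points after thinning, which lowers it by construction, 0.0 for calls at or above the median score and 0.26 within 300 bp, and the difference in mean neighbour distance went from 1.40 bp to 2.08 bp after thinning and -0.45 bp within 300 bp. Thinning also turned the ratio of arrays from 1.157 to 0.836; random loss of calls breaks runs by construction and does not imitate shallower sequencing. The alternatives for the periodicity contrast re-use the same calls and are not independent checks. Autosomes only (ratio 1.106) and leaving out chromosomes 8 and 12 (1.107) kept most of the calls. The periodicity contrast was higher with tamoxifen under 8 of 8 such alternatives. This leaves aside thinning, which removes pairs at all distances alike and cannot move the contrast. Its ratio of 1.107 moved beyond its counting interval to 1.138 for calls at or above the median score, 1.047 for calls with a partner within 40 bp, 1.137 for calls without one and 1.080 for pairs 340 to 430 over 240 to 330 bp apart, and was 1.095 for pairs 540 to 610 over 450 to 520 bp apart. Windows over 1.5-fold higher and lower fell from 9439 and 10738 to 22 and 9 at 100 kb, where there are fewer windows and more calls in each, and to 2795 and 2197 over 2-fold. Apart from these effects of construction the cause was not tested. No paired analysis was possible because each group has 1 library. The alternatives for motif sites and promoters were not run, for want of a genome and annotation of mm9. The unknown read depth limits each comparison of numbers of calls.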

Other observations

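All tests in this part were chosen after the results had been seen.

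Several regions held many nucleosome calls at the maximum score in both libraries, although most of the 757 ethanol and 848 tamoxifen calls at the maximum lay elsewhere. On chromosome 11 the window from 3000001 to 3100000 held 160 such calls with ethanol and 177 with tamoxifen, and the same interval of chromosome 9 held 64 and 54. On chromosome 8 the windows from 19700001 to 19800000 and from 19900001 to 20000000 held 44 and 45, and 30 and 36. The mitochondrial genome had 56 calls with ethanol and 58 with tamoxifen, of which 25 and 39 were at the maximum.

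The stronger periodicity in the tamoxifen library (contrast 1.546 against 1.397) was smaller, but still present, among calls with a partner within 40 bp. There the contrast was 1.692 (1.664 to 1.720) against 1.615 (1.589 to 1.642), a ratio of 1.047. Partners could lie up to 40 bp apart, so centres placed differently in the 2 libraries remain among them. A different choice of called positions therefore stays open. Greater read depth stays open, since reads were not counted: the contrast did not rise on the call-rich chromosomes 8 and 12 of the ethanol library, at 1.401 (1.374 to 1.430) beside 1.398 on the other autosomes, but calls stand in for reads there only if the excess comes from more reads. Within each library the contrast rose with local density, from 1.334 (1.278 to 1.391) in density classes 1 to 5 to 1.413 (1.396 to 1.429) in classes 9 and 10 with ethanol and from 1.426 (1.373 to 1.481) to 1.567 (1.550 to 1.585) with tamoxifen. On the X chromosome, which had the fewest calls per Mb, the contrast was below that of every autosome in each library. It was 1.150 (1.009 to 1.310) there with ethanol and 1.381 (1.224 to 1.559) with tamoxifen. The degree of MNase digestion cannot be told apart from the treatment with 1 digest per group, and the difference in mean call width of -0.02 bp does not decide it. An effect of Brg1 loss on nucleosome regularity may be a candidate explanation, was not tested against other cultures, and stays open beside choice of positions, depth and digestion. Effects of tamoxifen or of Cre itself cannot be told apart from it, because both libraries come from Brg1fl/fl cells. Loss of Brg1 was not measured here.

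The excess of calls on chromosomes 8 and 12 was present in both libraries. If these chromosomes were only richer in call-dense regions, their calls would score like those of other autosomes at the same local density, but in density class 9 of 10 their median scores were higher by at least 8.1. The excess was smaller in class 3, where the ethanol medians were 78.9 on chromosome 8 and 79.2 on chromosome 12 against 76.0. Extra copies of these chromosomes in the cell line may be a candidate explanation: at the same density, median scores on chromosomes 8 and 12 were above those of the other autosomes in 9 of the 9 classes in which they had calls, in each library. The excess was spread along the chromosomes, with 22 of 26 bins of 5 Mb on chromosome 8 and 19 of 24 on chromosome 12 above the median bin of the other autosomes in the ethanol library. Calls are not reads, so the ratios of 1.82 and 1.66 give no copy number, and the excess was similar with tamoxifen (1.81 and 1.68).

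The stretch of 8 ethanol calls on chromosome 9 without tamoxifen calls may mark the segment of Smarca4 that Cre removes, as Smarca4 lies on chromosome 9, which holds 5.37% of the ethanol calls. Its value of 5.13 was the highest of 340965 ethanol stretches. Calls missed by chance also stay open. A tamoxifen stretch, of 4 calls within 485 bp, reached 5.54, but no chance distribution of the value was computed. Among stretches of at least 8 calls within 5 kb the highest tamoxifen value was 3.36, a restriction chosen to match this stretch and therefore no independent evidence. The position of Smarca4 on mm9 and of its loxP sites was not used here, which keeps excision open.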
